A study of Arabidopsis thaliana with 8 samples.

How the data were processed

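Total RNA from rosettes of 8 Arabidopsis samples, labelled with biotin, was hybridised to Affymetrix ATH1 arrays, per the labels. The plants were grown in a chamber at 70% humidity and 22 °C by day and 19 °C by night and were 35 days old. The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes, and the MAS5 version is not given in the sources used here. All values were above 0, and the mean without the lowest and highest 2% of the 22810 probe sets was 99.96 on every array, so the authors' scaling to a common level was kept and the deposited intensity values were not rescaled. Each array was matched to its sample by its column name, and 0 columns lacked a sample. Arrays were grouped by their source name into Col-0 (2 arrays) and WRKY T-DNA knockout (6 arrays, each a different line). The disrupted gene of each line and the meaning of L and S in the Col-0 titles are not stated in the labels and were not inferred from the values.

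After removal of 64 control probe sets, 22746 remained. A pseudocount of 5, the rounded 20th percentile of all signals, was added before taking log2. Fold changes are therefore on the log2(signal + 5) scale, which understates the change of low genes. Probe sets whose mean log2 value over the 8 arrays lay above the 30th percentile were kept, 15922 in all. The platform annotation pairs 13513 of the 22746 probe sets with 1 gene symbol and 503 with several, and does not list 8730, which are called unlisted here and are not said to lack a gene. Symbols were updated through a gene table of the TAIR10.1 assembly, which held 13436 of the single-gene probe sets, and 8750 single-gene probe sets passed the filter. Genes with several probe sets were kept as separate items. No coordinates were used other than gene lengths and the order of neighbouring genes.

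Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The class comparison set the 6 lines against Col-0 with 6 residual degrees of freedom. Each line was compared with Col-0 in a model with 3 levels (the line, Col-0 and the other 5 lines) and 5 residual degrees of freedom, and the contrast of the line with the other 5 was read from the same model for the genes named. The Col-0 pair was compared in the same way as a background. Gene lists, of which the members past the filter were tested and counted, were tested with camera at a correlation of 0.01 between genes, again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in one direction without comparing them with other genes, each adjusted over the lists of a comparison. For list means an exact permutation test over the 28 splits of the arrays into 2 and 6 was used, whose smallest two-sided p is 0.0357.

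The comparisons, the filter, the pseudocount rule, the named genes rule and 21 gene lists, with the WRKY family among those tested, were chosen before the data were examined. Of the 291 genes in the fixed lists, 36 had a named probe set, so 8 fixed lists could be tested and 13 with fewer than 3 measured members were not. For that reason 19 lists of gene families and of plastid and mitochondrial genes were drawn from annotation symbols after the data were seen, which made 27 lists tested, and the result of 1 added list is not reported here. Named genes were, in the class comparison, the 10 largest rises and falls past the threshold, filled from the smallest unadjusted p where fewer passed, and in each line the 3 largest rises and falls past it, filled to 1 per direction. List members were to be named when past the threshold, up to 4 by size; members named without passing, and every probe set outside these rules, were chosen after their values were seen.

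The procedure was tested on simulated data with 15922 probe sets and 100 changed per fold size. In the class comparison 83% of changes of 2-fold and 100% of 4-fold were recovered, with 16 false calls, and in the comparison of KO-54 with Col-0 39% and 97%, with 7 false calls. The simulation drew noise independently for each probe set and array, without shared differences between lines or in RNA quality, and planted both fold sizes together. These shares therefore do not carry over to the real data. There AT1G47400 was 2.04-fold lower in the lines and was not called by limma (adjusted p = 0.406). The arrays' number limits the precision. RNA quality was checked with the 3' to 5' signal ratios of the actin, GAPDH and ubiquitin control probe sets and with the 25S ribosomal RNA control.

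Alternatives were a pseudocount of 1 or of 21 (the 40th percentile), no filter or a filter at the median (11373 probe sets), quantile normalization, centring of each array on its median, trended and robust variances, array weights, the spread of the Col-0 pair alone, each Col-0 array alone as control, and leaving out each array in turn. Leaving out KO-54 and KO-30, the 2 arrays with the highest actin and GAPDH 3' to 5' ratios (not the ubiquitin ratio), was added after seeing the data. Array values of unlisted probe sets were tested but described only where called or where they had the smallest adjusted p, in words and without their identifiers, and probe level files were not used here.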

Results

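Rosettes of Arabidopsis thaliana were profiled on 8 ATH1 arrays, an oligonucleotide array with 22746 probe sets besides its controls. Of these arrays, 2 held RNA of the reference accession Col-0, with titles ending in L and S that the labels do not explain, and 6 held RNA of plants with a T-DNA insertion in a WRKY gene. Each insertion line (KO-02, KO-07, KO-54, KO-40, KO-30 and KO-56) was measured on 1 array. The plants were 35 days old and had begun to bolt, and the sampled tissue was the rosette without stem and flowers. The trimmed mean signal was just under 100 on every array (99.96), and the array medians ran from 35.98 to 39.15. Pairs of arrays correlated across probe sets with r between 0.967 and 0.988, and the Col-0 pair with r = 0.984. The number of arrays limits the precision of every value. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which can be technical. That spread also holds differences between the 6 lines. A low number of calls can therefore partly reflect line differences counted as noise.

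The series concerns group II-A WRKY proteins, a branch of a plant-specific family of DNA-binding regulators, and early leaf senescence. The labels do not say which gene each insertion hits, and the numbers in the line names were not taken as gene numbers. No probe set was paired with WRKY18, WRKY40 or WRKY60, nor with WRKY2, WRKY7, WRKY54, WRKY30 or WRKY56, in the annotation used here. The level of a disrupted gene could therefore not be read in any line, and no line was checked against its label.

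RNA quality differed between arrays. The 3' to 5' signal ratio of the actin control, which grows as transcripts lose their 5' part, was 29.5 in KO-54 and 15.4 in KO-30, against 9.98 in Col-0-L and 10.9 in Col-0-S. The other 4 lines lay between 8.41 in KO-40 and 12.0 in KO-07. The GAPDH ratio was 2.46 in KO-54, 1.62 in KO-30 and between 1.21 and 1.44 on the remaining arrays. The ubiquitin ratio did not set these arrays apart: it was 2.74 in KO-54, 2.68 in Col-0-L and 2.49 in KO-30, with 2.41 in Col-0-S.

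**Figure D1:**
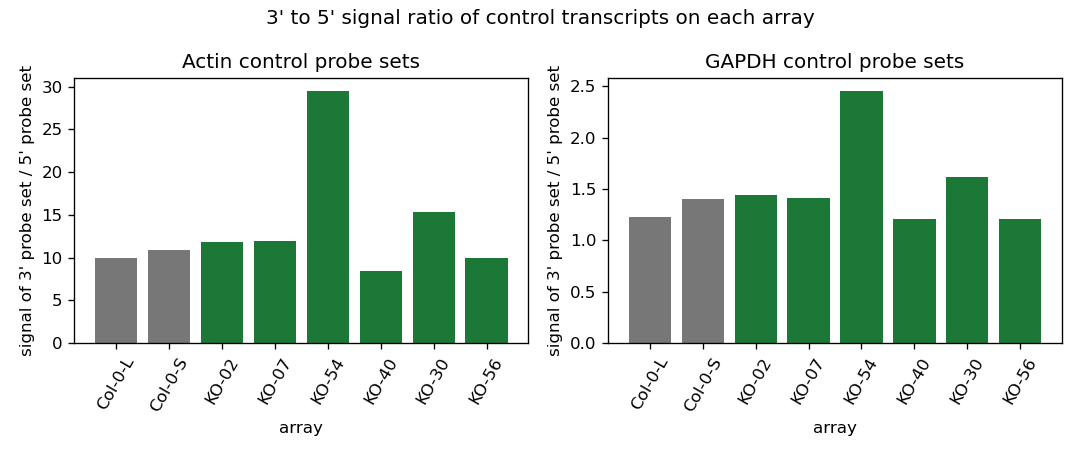
Ratio of the 3' to the 5' probe set signal (vertical axes, no unit) for the actin and GAPDH control transcripts, 1 bar per array, with Col-0 in grey and the knockout lines in green. KO-54 has the highest bar in both panels, at 29.5 for actin and 2.46 for GAPDH, and KO-30 the next, at 15.4 and 1.62.

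The comparison of the 6 lines with Col-0 asked what the insertion lines had in common. No gene list of iron responses was tested. AT1G47400, known to be induced by iron shortage, had a mean signal of 24.5 ± 2.39 (SD, n = 2) in Col-0 and 9.62 ± 2.27 (SD, n = 6) in the lines, a log2 difference of -1.03 ± 0.16 (SE). AT5G05250, also known from iron shortage, had 29.1 ± 9.19 in Col-0 and 13.6 ± 2.27 in the lines, a log2 difference of -0.86 ± 0.17. Other iron-response genes were nearly level, with -0.14 for PYE, -0.10 for AT3G56360, 0.03 for AT3G07720 and 0.03 for BHLH101, which lay below the filter. AT1G62500, a member of the lipid transfer protein family, had 133 ± 28.1 in Col-0 and 64.7 ± 16.8 in the lines, with a log2 difference of -1.01 ± 0.25. The thionin gene THI2.2, of a family of small antimicrobial peptides, had 76.2 ± 14.0 in Col-0 and 46.9 ± 7.97 in the lines, a log2 difference of -0.65.

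In the opposite direction, AT4G17150 had a signal of 17.5 ± 3.95 (SD, n = 2) in Col-0 and 32.8 ± 1.78 (SD, n = 6) in the lines, a log2 difference of 0.76 ± 0.12 (SE). Log2 differences among the other leading genes that were higher in the lines ran from 0.45 for AT4G00270 to 1.11 for AT1G12320, and included 0.75 for AT5G05130, 0.80 for AT1G32840, 0.52 for AT5G22690, 0.74 for AT3G04010, 0.96 for AT5G57480, 0.46 for AT5G17410 and 0.73 for AT1G12600. The remaining genes that were lower in the lines were AT2G31420 (-0.62), AT1G10640 (-0.73), AT1G56270 (-0.57), AT5G24480 (-0.57), AT1G19540 (-0.62) and AT4G30460 (-0.40). Each of these 20 genes, 10 per direction, lay beyond both Col-0 arrays in 6 of 6 lines.

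None of the 20 genes passed the test. limma called 0 of 15922 probe sets at an adjusted p under 0.05, with 593 at an unadjusted p under 0.05 (336 higher and 257 lower in the lines), where 796.1 are expected by chance. With trended and robust variances limma called 1 probe set. The adjusted p was 0.406 for AT1G47400 and AT4G17150 and from 0.914 to 0.989 for the other genes named. The smallest, 0.310, belonged to a probe set without a listed gene that was chosen after its values were seen and had a mean signal of 325 in Col-0 and 156 in the lines. All 6 lines lay below both Col-0 arrays for 494 probe sets and above both for 499, together 6.24% of those tested, where chance gives 7.14%.

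**Figure D2:**
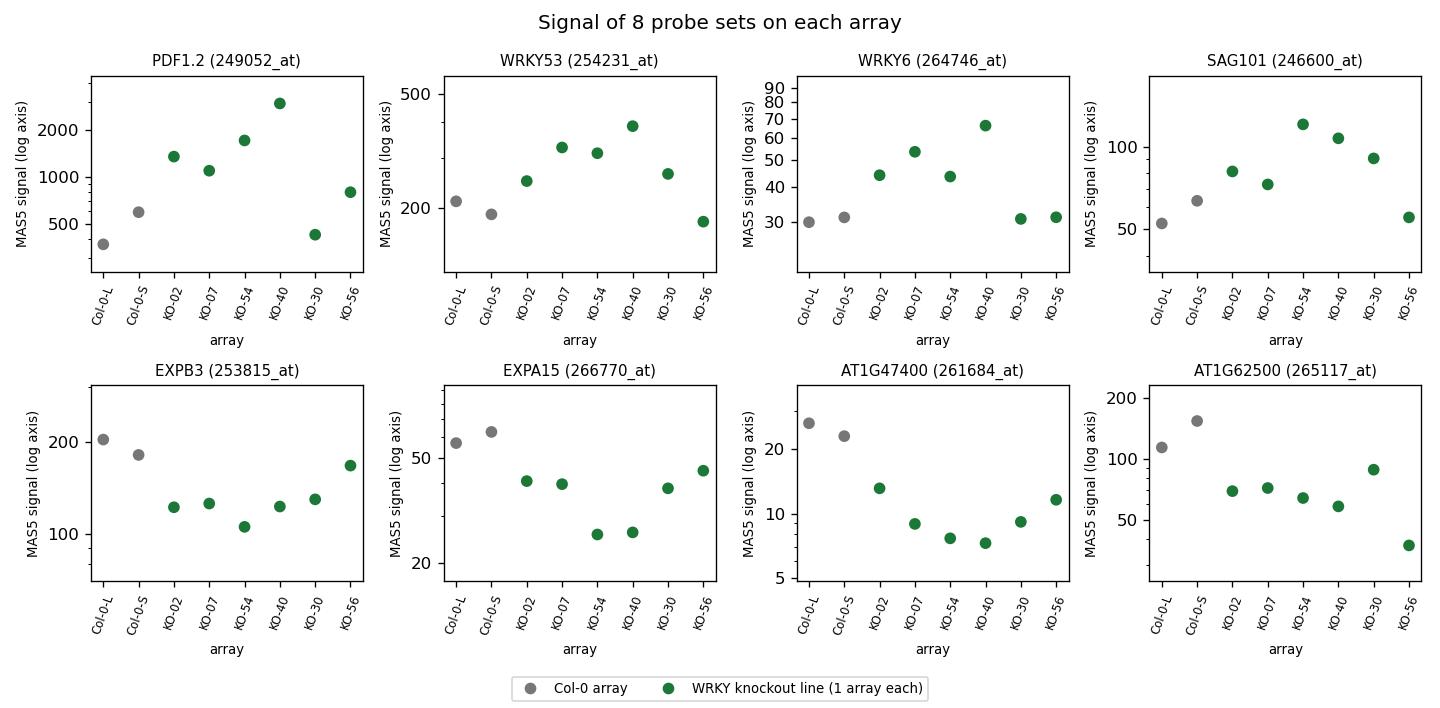
MAS5 signal (vertical axes, log scale, arbitrary units) of 8 probe sets on each array, with Col-0 in grey and the knockout lines in green. AT1G47400, AT1G62500, EXPB3 and EXPA15 lie below both Col-0 arrays in 6 of 6 lines, and the defensin gene PDF1.2 reaches 2945 in KO-40 against 368 and 592 in Col-0.

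The list called WRKY family holds only the WRKY genes that the annotation used here pairs with a probe set, not the whole family. As a group these genes were higher in the lines. All 5 of them past the filter, of 6 measured, had higher mean signals in the lines (median log2 difference 0.23). Their mean lay above both Col-0 arrays in 6 of 6 lines. WRKY53, a regulator that promotes leaf senescence, had 200.2 ± 14.9 (SD, n = 2) in Col-0 and 286 ± 71.9 (SD, n = 6) in the lines, a log2 difference of 0.46 ± 0.24 (SE). WRKY6, known from senescence and defence, had 30.6 ± 0.847 in Col-0 and 44.9 ± 13.5 in the lines, a log2 difference of 0.44 ± 0.24. WRKY47, WRKY22 and WRKY20 differed by 0.23, 0.09 and 0.09. The WRKY list passed camera, a test of a gene list against all other genes (adjusted p = 0.0236). The call was lost with an estimated correlation between genes (adjusted p = 0.402 with an estimated correlation). It was also lost without Col-0-L (median 0.11; adjusted p = 0.232) and without Col-0-S (median 0.35; adjusted p = 0.0538).

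Photosynthesis genes were lower in the lines, by a median log2 difference of -0.16 over 6 of 6 members, among them the light-harvesting gene LHCB4.1 (-0.19) and the Rubisco activase gene RCA (-0.16). This list passed camera (adjusted p = 0.0260; adjusted p = 0.491 with an estimated correlation), but its mean lay below both Col-0 arrays in 2 of 6 lines only. The median shrank to -0.02 without Col-0-L (adjusted p = 0.840) and to -0.05 after quantile normalization (0.661), and without KO-40 it was -0.12 (0.0844). The senescence list, which shares WRKY53, WRKY6 and WRKY22 with the WRKY family, had 4 of 5 members higher in the lines (median 0.44) and did not pass (adjusted p = 0.0817). Its member SAG101, an acyl hydrolase linked to senescence and immunity, had a log2 difference of 0.53 ± 0.24 and SAG29 one of -0.60 ± 0.41, and the list mean was above both Col-0 arrays in 4 of 6 lines. Without KO-56 that list reached an adjusted p of 0.0310 with camera. With the stricter filter it reached 0.00448, but not with the same members. SAG29, which went the other way and was dimmer than the array medians in Col-0, was too dim for that filter. Jasmonate and ethylene response genes had a median of 1.204, carried by the antifungal defensin genes PDF1.2 (1.31 ± 0.56) and PDF1.2b (1.204 ± 0.55), while the thionin gene THI2.1 had -0.02, and this list did not pass either (adjusted p = 0.0605). It passed without KO-30 (adjusted p = 0.0347), without KO-56 (adjusted p = 0.0432), with the higher pseudocount (0.0287), with the stricter filter (0.0344) and with arrays centred on their median (0.0386).

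The other lists fixed before the data were examined did not pass in this comparison. Median log2 differences were -0.19 for aliphatic glucosinolate genes, 0.22 for anthocyanin and flavonoid genes, -0.01 for abscisic acid and cold response genes and 0.02 for reference genes, with adjusted p between 0.156 and 0.959. No member of the 8 fixed lists tested passed over all probe sets, and 0 passed when adjusted over the list alone.

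Lists of gene families were drawn from the annotation after the data were seen. Autophagy genes, which act in the recycling of cell contents, were higher in 9 of 10 members (median 0.22), with their mean above both Col-0 arrays in 5 of 6 lines, and APG8A had 262 ± 6.44 (SD, n = 2) in Col-0 and 363 ± 62.6 (SD, n = 6) in the lines. Cytochrome P450 genes of the CYP71B group were higher in 10 of 11 members (median 0.19), including CYP71B23 (0.48 ± 0.19) and CYP71B29 (0.57 ± 0.16), and their mean lay above both Col-0 arrays in 6 of 6 lines. Cell wall loosening genes (expansins and XTH enzymes) were lower in 13 of 16 members (median -0.18), with their mean below both Col-0 arrays in 5 of 6 lines and above both in KO-30. The expansin genes EXPB3 and EXPA15 had 192 ± 15.6 and 59.7 ± 4.1 in Col-0 and 129 ± 20.4 and 35.9 ± 8.03 in the lines, log2 differences of -0.57 ± 0.15 and -0.69 ± 0.20, and these 2 passed when adjusted over the list alone but not over all probe sets. Endoglucanase (GH9) genes were lower in 5 of 6 members (median -0.32), with GH9B7 at -0.31 ± 0.11 and GH9C2 at -0.43 ± 0.19, and their mean lay below both Col-0 arrays in 6 of 6 lines (exact permutation test over 28 splits, two-sided p = 0.0357, the smallest possible, and 0.514 when adjusted over the 27 lists). UDP-glycosyltransferase genes, which attach sugars to small molecules, were higher in 22 of 29 members (median 0.04), UGT85A4 by 0.53 ± 0.18, with their mean above both Col-0 arrays in 5 of 6 lines and below both in KO-30.

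These families passed camera with adjusted p of 0.00139 (autophagy), 0.000799 (CYP71B), 0.00139 (cell wall loosening), 0.00628 (GH9) and 0.0483 (UDP-glycosyltransferases). The adjusted p were 0.468, 0.402, 0.402, 0.395 and 0.491 with an estimated correlation, in the same order, and 0 of 27 lists passed with fry (smallest adjusted p = 0.122). The exact permutation test gave unadjusted p of 0.0714 for CYP71B, 0.143 for autophagy, 0.25 for cell wall loosening and 0.214 for UDP-glycosyltransferase genes. It gave 0.107 for the WRKY family and 0.25 for photosynthesis genes, and each of these was 0.514 when adjusted over the 27 lists. Without Col-0-S the CYP71B, GH9 and UDP-glycosyltransferase calls were lost (adjusted p = 0.0718, 0.0652 and 0.573), the last with a median of 0.01. The GH9 call was lost without the filter on dim probe sets (0.154, median -0.16), and the UDP-glycosyltransferase call without KO-02, KO-07, KO-54 or KO-40 (0.0824, 0.0751, 0.0784 and 0.0844), with a pseudocount of 1 (0.0542) and after quantile normalization (0.0634).

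**Figure D3:**
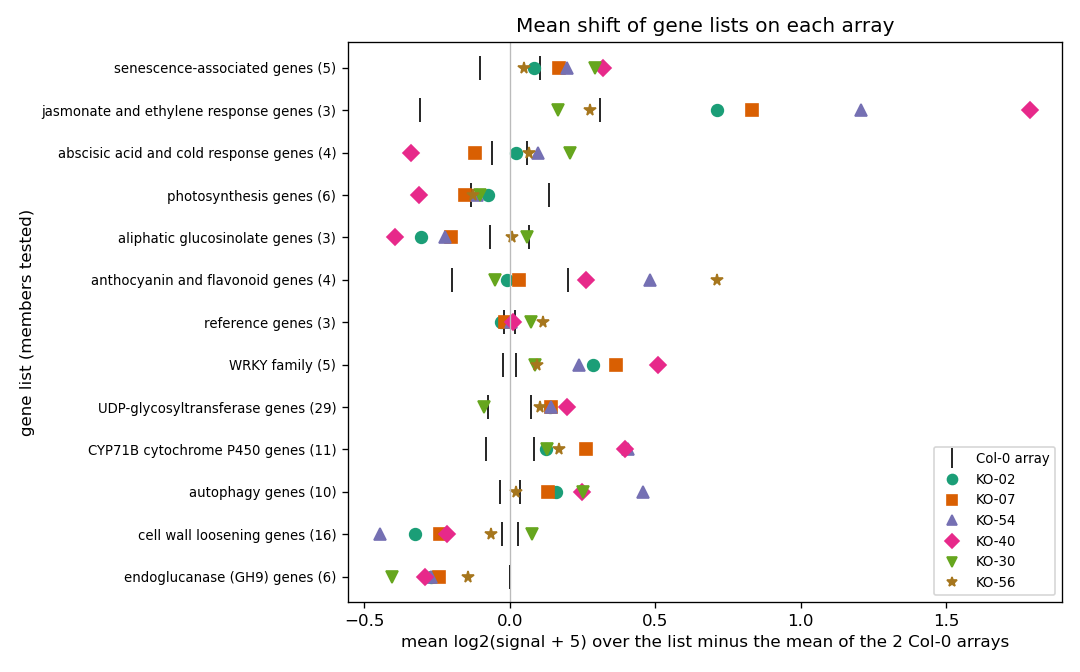
Mean log2(signal + 5) of each gene list minus its mean over the 2 Col-0 arrays (horizontal axis, log2 units), with the members tested in parentheses, black ticks for the Col-0 arrays and coloured markers for the lines. For the WRKY family all 6 lines lie to the right of both ticks and for GH9 genes all 6 lie to the left, while KO-40 has the largest jasmonate and ethylene shift at 1.79.

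Each line was then set against Col-0 to describe it on its own, with the spread pooled over the Col-0 pair and the other 5 lines. A lone array was thus assumed to vary like the others, and all line comparisons share the same 2 Col-0 arrays. Where list members are named in a line comparison, they were chosen as examples after their values were seen.

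In KO-54 3 transcripts of the chloroplast genome fell. The psaA transcript, encoding a core protein of photosystem I, had a signal of 567 against 2746 ± 689 (SD, n = 2) in Col-0, a log2 difference of -2.24 ± 0.22 (SE; adjusted p = 0.0192). The rpoB transcript, encoding a subunit of the plastid RNA polymerase, had 5.95 against 52.5 ± 15.0 (-2.37 ± 0.28; adjusted p = 0.0342). The nuclear gene SIZ1, a SUMO ligase with a part in stress and hormone responses, fell to 10.9 from 59.6 ± 6.20 (-2.02 ± 0.19; adjusted p = 0.0192), and AT1G17490 rose to 307 from 122 ± 7.91 (1.296 ± 0.16; adjusted p = 0.0347). This array also had the highest actin and GAPDH 3' to 5' ratios, 29.5 and 2.46.

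limma called 11 probe sets in KO-54, 1 higher and 10 lower, and 1676 at an unadjusted p under 0.05. Beyond the genes above, chosen after their values were seen, these were ndhH of the chloroplast NDH complex (32.3 against 114 ± 4.52, -1.67), AT1G53800 (-1.30), AT2G28540 (-1.73), AT1G23205 (-1.62), a probe set shared by AT3G23530 and AT3G23510 (-2.46), and 2 unlisted probe sets (-1.44 and -3.21). The fall of AT1G23205 was not particular to KO-54. Its signal was 25.7 ± 1.42 (SD, n = 2) in Col-0 and between 11.5 and 16.9 in the other 5 lines. From those lines KO-54 differed by -0.90. Neighbours of the plastid genes in the same transcription units gave other values. The gene psaB, downstream of psaA, had -0.12, and rpoC1 and rpoC2, downstream of rpoB, had -0.00 and 0.34. The number called was 0 without Col-0-L, KO-02 or KO-40, 1 without KO-07 or Col-0-S, 20 with a pseudocount of 1, 7 with the higher pseudocount, 18 with trended and robust variances and 0 without the filter. With the higher pseudocount the calls of rpoB (-1.43; adjusted p = 0.0530), AT1G53800 (-0.88; 0.0602), AT2G28540 (-0.83; 0.137), AT1G23205 (-0.85; 0.0940) and the unlisted probe set at -3.21 (-2.34; 0.0530) were lost. With KO-30, the array with the next highest actin and GAPDH 3' to 5' ratios, left out, 10 were called, and rpoB and AT1G17490 had adjusted p of 0.0578 and 0.0531.

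Plastid-encoded photosynthesis genes as a list were lower in KO-54 in 29 of 43 members (median -0.13, mean -0.30), with 2 members, psaA and ndhH, past the threshold over all probe sets and 8 when adjusted over the list alone. Among the latter, psbD had a log2 difference of -1.72 ± 0.28, psaC one of -1.25 ± 0.19 and psbB one of -1.15 ± 0.30. Autophagy genes were higher in 9 of 10 members (median 0.55), with APG8A at 459 against 262 ± 6.44 (SD, n = 2), a log2 difference of 0.80 ± 0.21, and APG8H and ATG8E at 0.63 ± 0.17 and 0.67 ± 0.22, these 3 passing when adjusted over the list alone. CYP71B genes were higher in 10 of 11 members (median 0.43). Cell wall loosening genes were lower in 15 of 16 members (median -0.40), with EXPA15 at -1.08 ± 0.26 and EXPB3 at -0.83 ± 0.21, the 2 that passed over the list alone. Camera gave adjusted p of 0.00547 for the plastid list, 5.28e-05 for autophagy, and 0.000557 for both the CYP71B and the cell wall list, and each call was lost with an estimated correlation (adjusted p = 0.787, 0.341, 0.341 and 0.341 with an estimated correlation). The plastid median shrank to -0.01 without Col-0-L (adjusted p = 0.148) and to -0.01 after quantile normalization (0.0431), and without the filter the CYP71B list had 0.0797 with a median of 0.25. The actin 3' to 5' ratio of 29.5 on this array stood beside all 4 list shifts.

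**Figure D4:**
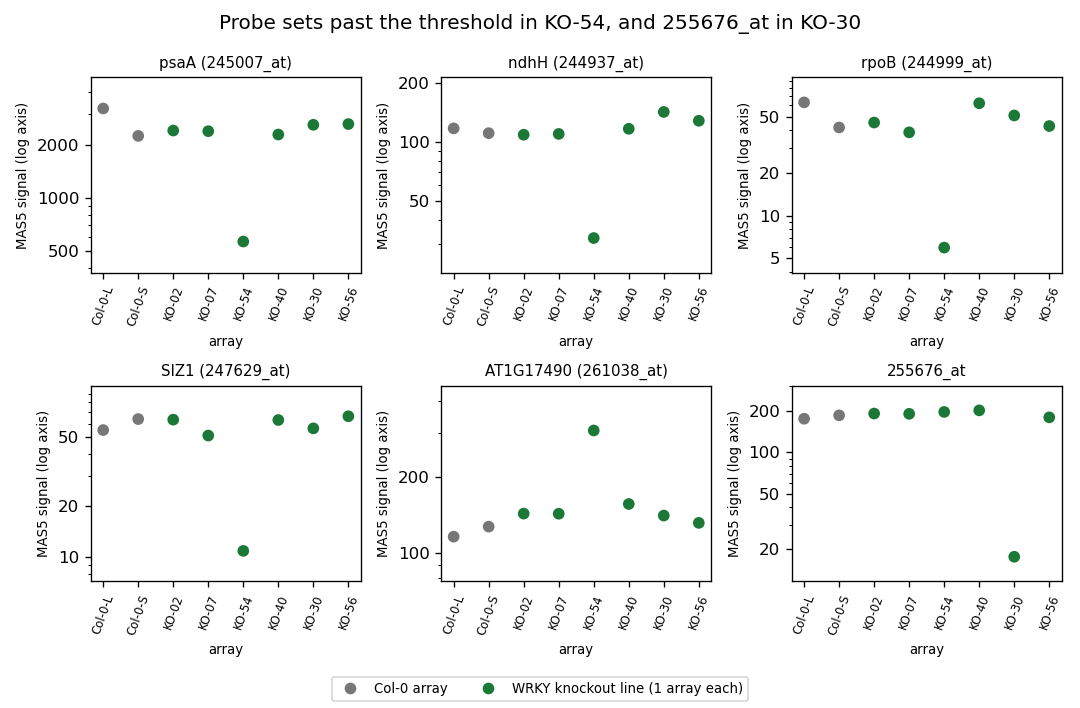
MAS5 signal (vertical axes, log scale, arbitrary units) on each array for 5 genes called in KO-54 and for the unlisted probe set called in KO-30, with Col-0 in grey and the lines in green. In KO-54, psaA is at 567 where the other 5 lines lie between 2299 and 2637, and in KO-30 the unlisted probe set is at 17.59 where no other array is under 175.

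In KO-40 the jasmonate and ethylene, senescence and WRKY lists were higher with the fixed correlation of camera, although none of these lists passed with an estimated correlation and no single gene passed over all probe sets. PDF1.2 had a signal of 2945 against 480.1 ± 158 (SD, n = 2) in Col-0, a log2 difference of 2.64 ± 0.67 (SE), and PDF1.2b had 2525 against 439 ± 103 (2.53 ± 0.63), while THI2.1, the other member of the jasmonate list, had 0.19 ± 0.53. WRKY53 had 387 against 200.2 ± 14.9 (0.94 ± 0.31), WRKY6 had 66.1 against 30.6 ± 0.847 (1.00 ± 0.29), and SAG101 had 107 against 58.0 ± 7.76 (0.84 ± 0.35). SAG29, with the largest difference in the senescence list, went the other way, with 6.68 against 24.6 ± 10.6 (-1.30 ± 0.58). Lists in the opposite direction held photosynthesis genes, with RCA at -0.38 ± 0.19 and LHCB4.1 at -0.33 ± 0.17, and abscisic acid and cold response genes, with the chloroplast cold-protection gene COR15A at -0.45 ± 0.21.

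Of 27 lists, 12 passed camera in KO-40, 7 upward and 5 downward, and 6 of these had been fixed before the data were examined. Upward were the jasmonate and ethylene list (median 2.53, 3 of 3 members, adjusted p = 0.00552), the senescence list (0.84, 4 of 5, adjusted p = 0.0317) and the WRKY family (0.47, 5 of 5, adjusted p = 0.00628), all lost with an estimated correlation (adjusted p = 0.283, 0.293 and 0.283 with an estimated correlation). Downward were photosynthesis genes (-0.31, 6 of 6, adjusted p = 0.00408), abscisic acid and cold response genes (-0.33, 4 of 4, adjusted p = 0.0166) and aliphatic glucosinolate genes (-0.38, 3 of 3, adjusted p = 0.0305), also all lost (adjusted p = 0.387, 0.340 and 0.340 with an estimated correlation). Over all probe sets 0 members passed, while adjusted over the list alone 2 passed in the jasmonate and ethylene list (PDF1.2 and PDF1.2b) and 2 in the senescence list and the WRKY family alike (WRKY53 and WRKY6). The photosynthesis, abscisic acid and glucosinolate calls were lost after quantile normalization (camera adjusted p = 0.576, 0.0988 and 0.0872), where the photosynthesis median was -0.05. They were also lost without Col-0-L, where the medians were -0.18, -0.25 and -0.38. The senescence call was lost without Col-0-L (median 0.71) or without KO-30 (camera adjusted p = 0.0659).

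Among families drawn after the data were seen, CYP71B genes had a median of 0.23 in KO-40 (adjusted p = 0.00229; 0.340 with an estimated correlation), with CYP71B22 at 0.99 ± 0.17 and CYP71B23 at 0.90 ± 0.23 among 4 members passing when adjusted over the list alone. Calmodulin-like and plant U-box genes, of calcium signalling and protein turnover, had a median of 0.26 (adjusted p = 0.00628; 0.293 with an estimated correlation), with CML41 at 1.18 ± 0.30 and PUB23 at 1.03 ± 0.26. Autophagy genes had 0.20 in 10 of 10 members (adjusted p = 0.0229; 0.506 with an estimated correlation) and UDP-glycosyltransferase genes 0.11 (adjusted p = 0.0305; 0.506 with an estimated correlation). Cell wall loosening and serine carboxypeptidase-like genes had medians of -0.19 each (adjusted p = 0.0202 for both; 0.489 and 0.283 with an estimated correlation). Without Col-0-L the autophagy call was lost (0.0734), without Col-0-S (0.213) or with the stricter filter (0.0534, median 0.05) the UDP-glycosyltransferase call, and without the filter the cell wall and carboxypeptidase calls (0.0689 and 0.264, with medians of -0.07 and -0.05).

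Over single probe sets limma called 0 in KO-40, with 1064 at an unadjusted p under 0.05 (631 higher and 433 lower). The peroxidase gene Prx37 led with 67.6 against 17.3 ± 2.72 (SD, n = 2), a log2 difference of 1.71 ± 0.22 (SE; adjusted p = 0.160), followed in the other direction by AT1G72250 with 5.598 against 20.7 ± 3.51 (-1.27 ± 0.19; adjusted p = 0.161). The count was 4 with the higher pseudocount, where Prx37 had an adjusted p of 0.0431, 25 with the spread of the Col-0 pair alone, 1 with trended and robust variances, 3 without KO-30 and 1 without KO-56.

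In KO-30 a single probe set fell. The probe set, without a listed gene and chosen after its values were seen, had a signal of 17.59 against 180.4 ± 7.20 (SD, n = 2) in Col-0, a log2 difference of -3.04 ± 0.14 (SE; adjusted p = 0.000108). The remaining lines had 192 ± 8.24 (SD, n = 5), and the difference of KO-30 from them was -3.12. The leading named genes, AT1G09575 of the mitochondrial calcium uniporter family (0.99 ± 0.19; adjusted p = 0.446) and AT1G02575 (-1.08 ± 0.15; adjusted p = 0.326), did not pass, and 1350 probe sets had an unadjusted p under 0.05.

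Plastid-encoded genes were higher in KO-30 as lists, by a median of 0.13 over the photosynthesis genes (34 of 43 members higher, adjusted p = 0.00144) and of 0.28 over the ribosome and RNA polymerase genes (16 of 19, adjusted p = 0.00870), both lost with an estimated correlation (adjusted p = 0.831 with an estimated correlation). Autophagy genes were higher by a median of 0.22 in 8 of 10 members (adjusted p = 0.0356; adjusted p = 0.831 with an estimated correlation), with ATG8E at 0.66 ± 0.22 and APG8A at 0.61 ± 0.25. In these 3 lists 0 members passed over all probe sets or when adjusted over the list alone. The photosynthesis call was lost without Col-0-S (0.211), where its median was 0.03, the ribosome call without Col-0-L (0.0982) and after quantile normalization (0.0799), and the autophagy call without Col-0-L (0.0982), without Col-0-S (0.110) and after quantile normalization (0.0799). The actin 3' to 5' ratio of this array, 15.4, was above those of Col-0.

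In KO-56 genes of anthocyanin and flavonoid synthesis were higher as a list, by a median of 0.58 in 4 of 4 members. The glycosyltransferase gene UF3GT had a log2 difference of 1.14 ± 0.41 (SE), the reductase gene DFR one of 0.54 ± 0.31 and the malonyltransferase gene AT5MAT one of 0.56 ± 0.33. The list passed camera (adjusted p = 0.0121; adjusted p = 0.813 with an estimated correlation), while 0 members passed over all probe sets and 0 when adjusted over the list alone. The call was lost without Col-0-L (0.184) and without the filter (0.0633), and the median ran from 0.43 to 0.91 over the alternatives. The Col-0 arrays differed on this list by more than the 0.58 of KO-56, with a median of -0.67 for Col-0-L minus Col-0-S, with UF3GT at -0.93 and DFR at -0.84, without passing (adjusted p = 0.313).

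limma called 1 probe set in KO-56, an unlisted probe set chosen after its values were seen, which fell to 2.22 from 17.0 ± 0.514 (SD, n = 2), a log2 difference of -1.61 ± 0.17 (SE; adjusted p = 0.0468). The gene 4CL8, of the family of coumarate-CoA ligases, had 50.7 against 14.7 ± 1.90 (1.51 ± 0.19; adjusted p = 0.123), and AT4G16610 had 3.59 against 21.1 ± 1.52 (-1.60 ± 0.23; adjusted p = 0.123). At an unadjusted p under 0.05 there were 876 probe sets. The call was lost without any array except KO-54, whose omission gave 3 calls, and with the higher pseudocount, the stricter filter or trended and robust variances, and the count was 6 without the filter.

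In KO-02 cell wall loosening genes were lower in 14 of 16 members (median -0.32), with EXPB3 at -0.63 ± 0.24 (SE) and EXPA15 at -0.50 ± 0.30. This list passed camera (adjusted p = 0.000298; adjusted p = 0.612 with an estimated correlation), with 0 members passing over all probe sets or over the list alone. limma called 0 probe sets and 364 had an unadjusted p under 0.05. The leading genes were AT5G10830, with 3.03 against 22.5 ± 3.68 (SD, n = 2) in Col-0 (-1.77 ± 0.23; adjusted p = 0.388), and AT4G17150 (0.86 ± 0.19; adjusted p = 0.999).

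In KO-07 the WRKY family was higher in 4 of 5 members (median 0.46), with WRKY6 at 0.71 ± 0.36 (SE) and WRKY53 at 0.69 ± 0.36, and CYP71B genes were higher in 9 of 11 (median 0.25). Cell wall loosening genes were lower in 14 of 16 members (median -0.22). Camera gave adjusted p of 0.0400 for the WRKY family and 0.00931 for both other lists, all 3 with an adjusted p = 0.546 with an estimated correlation, and 0 members passed over all probe sets or when adjusted over the list alone. The WRKY call was lost without Col-0-L (median 0.34) or Col-0-S (median 0.58). It was also lost without KO-02 (camera adjusted p = 0.0516), KO-54 (0.0610), KO-30 (0.0715) or both KO-54 and KO-30 (0.104). The other calls were lost without Col-0-S, with medians of 0.23 for CYP71B and -0.35 for the cell wall list. Without the filter they were lost too, with medians of 0.15 and -0.17 (camera adjusted p = 0.191 for both). limma called 0 probe sets with 263 at an unadjusted p under 0.05, and 1 with the spread of the Col-0 pair alone, and the leading genes AT1G49210 (0.84 ± 0.21) and AT2G23700 (-0.99 ± 0.21) had adjusted p of 1.00.

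Photosynthesis genes also separated the Col-0 arrays. They were higher in Col-0-L than in Col-0-S in 6 of 6 members (median 0.27), and plastid-encoded photosynthesis genes in 35 of 43 (median 0.22), each with a camera adjusted p of 0.0223 and an adjusted p = 0.869 with an estimated correlation. limma called 0 probe sets between these arrays, with 520 at an unadjusted p under 0.05.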

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

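The tests of the array floor and of dim-probe noise, and the test of the length of the 4 nuclear genes, were chosen only after the results were seen. Among 73 sets of 6 line values checked for a line far from the others, 25 passed the critical Dixon gap ratio for 6 values, where chance gives about 1 in 20, or 3.65. The named probe sets among them, 19, had been picked for their size or their call in a comparison, which raises this number.

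In KO-54 the gap to the nearest other line, as a share of the range over the 6 lines, was 0.911 for psaA, 0.764 for rpoB, 0.813 for ndhH, 0.841 for SIZ1, 0.837 for AT1G53800, 0.787 for AT2G28540, 0.636 for AT1G23205, 0.766 for the probe set shared by AT3G23530 and AT3G23510, and 0.739 and 0.726 for 2 unlisted probe sets, all lowest, and 0.797 for AT1G17490, which was highest. In limma's test against the other 5 lines KO-54 differed in psaA (-2.11), rpoB (-2.26), ndhH (-1.75), SIZ1 (-2.03), AT1G53800 (-1.16), AT2G28540 (-1.65), the shared probe set (-2.32), the same 2 unlisted probe sets (-1.38 and -3.23) and AT1G17490 (1.07), all log2 differences. AT1G23205 (-0.90) did not pass there. These probe sets had been picked for their difference from Col-0 on the same array and in the same model, so most were bound to differ. The same holds for the KO-30 and KO-56 contrasts below. The KO-54 array was highest in the actin 3' to 5' ratio (gap 0.671), the GAPDH ratio (0.672) and the 25S ribosomal RNA control (0.662). The signal of that control, 978.6, compares with 250.4 and 303.1 in Col-0.

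For the lower signals of KO-54, a position near the floor of the array is not decided. The probe sets that fell had a median Col-0 signal of 56.1, but a dim probe set could hardly be called as a fall. In KO-54 itself rpoB had 5.95 and AT2G28540 3.03, near the pseudocount of 5, while others lay higher, such as psaA at 567. Over 8643 nuclear genes the change correlated with gene length by a Spearman rho of -0.0306, while KO-30, with a lower actin ratio, had -0.23. RNA shortening thus showed no trend with gene length over all nuclear genes in KO-54. Gene length is not the distance of a probe set from the 3' end, which was not used, so shortening is not excluded. An effect on part of the nuclear genes stays open, as the 512 nuclear probe sets with an unadjusted fall had a median gene length of 2515.5 bp and the 382 with an unadjusted rise 2128 bp, against 2345 bp over all. RNA shortened from the 5' end stays open for the plastid transcripts, where rho was -0.36 across 69 genes (permutation p = 0.00267, genes not being independent replicates), though it reached 0.40 in Col-0-L, whose actin ratio was not raised, and was 0.17 in KO-30, and for the 4 nuclear genes SIZ1, AT1G53800, AT2G28540 and AT1G23205, whose median length lay at percentile 97.9 of random lists matched on signal. Of these 4 nuclear genes, AT1G23205 was lower than in Col-0 in the other lines as well. Length alone does not order the plastid genes. Short ones went both ways, with psaC and atpH (246 bp each) at -1.25 and -1.20 and rpl36 (114 bp) at 1.07. The longest listed, rpoC2 with 4131 bp, had a log2 difference of 0.34. Since rpoC2 lies downstream of rpoB in the same transcription unit, loss of the 5' part could spare it. Its value therefore does not speak against shortening. Shortened RNA is thus a candidate explanation for part of the pattern, and an effect of the insertion is another that could not be tested with 1 array of the line.

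In KO-30 the unlisted probe set called in that line had a gap ratio of 0.949 and a log2 difference of -3.12 from the other 5 lines. The test for noise of a dim probe set could hardly come out otherwise. With a pseudocount of 5, a dim probe set could not have shown a fall of this size. The lowest signal on the other 7 arrays was 175, which shows only that the probe set was not dim there. A fault on a part of the KO-30 array and a transcript lost from this line cannot be told apart: 0 other probe sets above 50 on the other 7 arrays were at least 4 times below their lowest value there, but spot positions were not used here, so a small fault stays open. The call held under all 18 alternatives run for it, with log2 differences from -3.29 to -2.38. A change of the target sequence or a deletion carried by the line may also lower such a probe set and was not tested.

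In KO-56 the unlisted probe set called in that line had a gap ratio of 0.858 and differed from the other 5 lines by -1.54, and 4CL8 had a gap ratio of 0.761 and differed by 1.35. The gap ratio of AT1G19540, highest in KO-56, was 0.633. In KO-02 AT5G10830 was lowest with 0.736. In KO-40 Prx37 was highest with 0.691, AT1G72250 lowest with 0.764, and the mean of the photosynthesis genes lowest with 0.661. KO-30 was lowest in AT1G02575 (0.789), in the mean of the UDP-glycosyltransferase genes (0.673) and in that of the vacuolar processing enzyme and subtilase genes (0.681). The 25S ribosomal RNA control, outside the main measurement, was 377.5 in KO-30, above both Col-0 arrays.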

How the results depend on the processing

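The alternative without KO-54 and KO-30 and the family lists were chosen after seeing the data, and all others before. The 43 results for named genes were each checked under their alternatives, which made 715 checks. In 590 of these checks the result kept its direction and side of the threshold, in 123 it fell below the threshold and in 2 it passed. All 123 losses came from probe sets called in the main analysis. The other results had not passed there and mostly kept their side by still not passing. Among the called ones, rpoB in KO-54 kept its call in 6 of 18 alternatives. The unlisted probe set of KO-56 kept it in 5 of 17, and that of KO-30 in 18 of 18. The 51 list shifts were checked in the same way, which made 889 checks. In 813 of these the list kept its side of the threshold, though some lists that did not pass changed sign. In 64 the list fell below the threshold and in 12 it passed. No result passed the threshold in the opposite direction.

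Counts of probe sets moved as follows, and the cause was not tested. With a pseudocount of 1, KO-54 had 20 in place of 11. With the higher pseudocount KO-54 had 7, KO-40 4 and KO-56 0. Without the filter KO-54 had 0, KO-30 2 and KO-56 6, and with the stricter filter KO-56 had 0. Trended and robust variances gave 18 in KO-54, 1 in KO-40, 0 in KO-56 and 1 between all lines and Col-0. The spread of the Col-0 pair alone gave 0 in KO-54, 25 in KO-40, 1 in KO-07 and 0 in KO-56. Col-0-L alone as control gave 1 in KO-54 and 0 in KO-56, and Col-0-S alone gave 0 in both. Without KO-54 and KO-30 as other lines KO-56 had 0, KO-54 had 10 and 8 lists passed between the remaining lines and Col-0. Of 27 lists, 7 passed between the lines and Col-0, and 0 with an estimated correlation and 0 with fry. Leaving out each array in turn gave 0 to 14 probe sets in KO-54, 0 to 3 in KO-40, 0 to 3 in KO-56 and 3 to 10 lists between the lines and Col-0, the lowest without Col-0-S and the highest without KO-56. In KO-54 the count was 0 without Col-0-L, KO-02 or KO-40. Array weights gave 0 probe sets between the lines and Col-0.

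No paired analysis was possible because every title carries the same replicate number, so the groups share fewer than 2 numbers. Signal over background limits the dim probe sets: the pseudocount shrinks their differences, as the unlisted probe set called in KO-56 went from -1.61 to -0.71 with the higher pseudocount.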

Other observations

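The gene families were drawn after the data were seen, so their tests were chosen only then.

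Other genes of defence, pigment and cell wall pathways gave further values in single lines. In KO-40 the zinc finger gene STZ, which responds to stress, had a log2 difference from Col-0 of 0.92 ± 0.30 (SE), and the glutaredoxin gene GRX480, known from salicylic acid responses, had 0.86 ± 0.34. The chlorophyll synthesis genes PORB and CHLM had -0.46 ± 0.19 and -0.45 ± 0.17 in the same line, and the beta-glucosidase gene BGLU47 had a signal of 9.64 against 37.7 ± 1.62 (SD, n = 2) in Col-0 (-1.54 ± 0.24; limma adjusted p = 0.161). In KO-54 the beta-glucosidase PYK10, a marker of roots, had 19.9 against 50.3 ± 11.4 (-1.14 ± 0.20; limma adjusted p = 0.145). In KO-30 the subtilase genes SBT3.12 and SBT3.5, encoding proteases, had log2 differences of -1.22 ± 0.17 and -0.75 ± 0.23, and these 2 passed when adjusted over their list alone but not over all probe sets (adjusted p = 0.326 and 0.470). In KO-56 the expansin-like gene EXLB1 had 191 against 120.4 ± 0.147 (0.65 ± 0.16) and the XTH gene XTH33 had 3.67 against 13.4 ± 2.34 (-1.08 ± 0.27), with limma adjusted p of 0.4001 and 0.427.

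The other families described here did not pass between the lines and Col-0. Median log2 differences ran from -0.10 for tubulin genes to 0.12 for calmodulin-like and plant U-box genes, with adjusted p from 0.127 to 0.959. Between these lay the plastid-encoded photosynthesis genes, plastid-encoded ribosome and RNA polymerase genes, mitochondrion-encoded genes, glutathione S-transferase genes, vacuolar processing enzyme and subtilase genes, SWEET sugar transporter genes, TBL polysaccharide acetylation genes, tetraspanin genes, beta-glucosidase genes, serine carboxypeptidase-like genes, and ubiquitin protease and conjugating enzyme genes. Tubulin genes passed without KO-30 (adjusted p = 0.0301), and calmodulin-like and plant U-box genes without KO-56 (0.0145) and with the stricter filter (0.00865).

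For the 593 probe sets with an unadjusted p under 0.05 between the lines and Col-0, 16 of the 28 splits of the 8 arrays into 2 and 6, the real split included, gave as many. Chance could therefore not be excluded. The highest other split, KO-54 and KO-40 against the remaining arrays, gave 1863, several times the real count. Other splits that group the arrays differently gave nearly as many (1836 for KO-30 and Col-0-S, 1793 for KO-54 and KO-30, 1670 for Col-0-L and KO-56). The arrays therefore differ in ways that the line and Col-0 groups do not describe, and which structure lies behind this was not tested.

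The iron-deficiency genes AT1G47400 and AT5G05250, lower in 6 of 6 lines without passing the test, were weighed against RNA quality and against a general iron response. RNA quality is not decided for AT1G47400. Its mean log2 difference was -1.05 in KO-40 and KO-56, the lines whose actin 3' to 5' ratios were no higher than in Col-0. But the gene was picked for its small p over all lines, so a clear fall in these lines too was nearly given. A weaker iron-deficiency response may lie behind the pattern, but the median log2 difference of BHLH101, PYE, AT3G56360 and AT3G07720 was -0.0318. That lies above the bound of -0.1 set beforehand against this explanation, but by less than the spread of the 4 genes, so it does not decide. BHLH101 had a signal of at most 1.87 on any array, which leaves 3 genes, and these went both ways, from -0.14 for PYE to 0.03 for AT3G07720. The iron supply of the plants is not given in the labels, so a weaker response and a difference in iron supply between pots cannot be told apart.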
